A study of Mus musculus with 25 samples.

How the data were processed

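Gene-level read counts for 25 libraries, as deposited by the authors, were analysed; the deposited table holds 13641 genes and 4 construct sequences (CreERT2, human JAK2 in 2 parts and pEGFP). Per the labels, RNA was extracted with PicoPure, polyA RNA was amplified with SMART-Seq v4 and libraries were unstranded. The submitters' processing notes name mm10, FastQC 0.11.5, STAR 2.7.10a, R 4.2.2 and featureCounts, whose version is not stated. Columns were matched to samples by genotype and replicate number in their names. Library totals in counts were 26722287 to 28799494 (WT_2w), 21990959 to 31488657 (VF_2w), 26607966 to 31968194 (VF_4w), 26398242 to 29835071 (Il1bKO_2w), 27077619 to 40178173 (Il1bKO_4w), 25615916 to 31238212 (Il1r1KO_2w) and 24328608 to 27920010 (Il1r1KO_4w). Libraries are named by genotype, week and the replicate number of their titles. The lowest maximum count of a gene over the libraries was 32 and the lowest total 69, so genes with fewer reads had been left out before deposit. Symbols and mm10 positions came from GENCODE vM21 for 13623 of the genes, of which 13590 were protein-coding. Reads were not realigned, and exon-level reads of the knockout alleles are not analysed here.

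Genes were tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood fit, 13630 genes tested) in 1 fit of 7 groups of genotype and time, and p was adjusted by Benjamini-Hochberg at 0.05. The constructs were left out of the gene tests. The common dispersion was 0.169 (coefficient of variation 0.411). Differences over both times were means of the 2 within-time differences, and time dependence was tested as the difference of these. CPM and SD are over libraries, log2 fold changes and SE are those of the fit, and folds against a group without reads are given as at least N-fold against a floor of 3 counts over the group. Such floors cover counting error only. Comparisons, tests, gene lists and alternatives were fixed before the data were examined, apart from those said to have been added.

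Of 28 gene lists written from general knowledge, 27 with at least 5 tested members were tested with camera (limma 3.58.1, log2 CPM with prior count 2, preset correlation 0.01), with camera at an estimated correlation and with fry, adjusted over the lists. They covered the IL-1 pathway, NF-kB and TNF targets, JAK-STAT targets, type I interferon, interferon gamma, MHC class II, stem cell, quiescence, megakaryocyte, erythroid, neutrophil and monocyte, mast, basophil and eosinophil, macrophage and dendritic, B lineage, T and NK, and endothelial and stromal genes. The rest were S phase, G2 and M phase, MYC targets, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, cholesterol synthesis, unfolded protein response, p53 targets and immediate early genes. Members were also adjusted over their list alone.

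Named genes followed a rule: Il1b, Il1r1, Jak2, Il1a, Il1rn, Socs2, Cish and Pim1 always; then the 8 lowest adjusted p per direction among called genes with mean log2 CPM of at least 1 and a proper symbol (5 in secondary comparisons); then up to 4 called members per list. Where fewer than 5 genes were called, those of lowest p were named as not passing. Constructs and Echdc2 were compared by exact permutation of genotype within time (two-sided, mean log2 CPM difference, adjusted over 20 tests). These permutation tests were added to the plan, and Echdc2 was chosen from these data. Called genes near Il1b and Il1r1 were counted within 20, 10 and 5 Mb and tested with Fisher's exact test, and the tested genes within 1 Mb were listed.

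Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma voom with quality weights, no filter, a filter of CPM 5 in 3 libraries, a fit of the compared groups alone, the replicate number as a block, and each library left out in turn. Added after the data were seen were fits without VF_4w 6, Il1bKO_4w 5 and Il1r1KO_4w 5, without WT_2w 3 and WT_2w 4, and with the 16 libraries of 2 weeks only. Shared VF libraries were handled by 12 simulations of unchanged groups and by dividing the VF libraries of 2 weeks between the comparisons. Library labels were also split so that each new group mixed the true groups, and calls were counted again. The pipeline was tested on simulated data of the same design. Of 100 genes changed by log2 1 and 100 by log2 2, the test recovered 67 and 86 in VF against WT, 68 and 96 in Il1bKO against VF, 74 and 97 in Il1r1KO against VF, and 76 and 90 between the knockouts. Unchanged genes called numbered 11, 8, 14 and 3. A list shifted by log2 0.5 was called with 0 other lists. The simulated genes varied independently, no simulated library stood apart, and changed genes were drawn from the better counted ones. These rates therefore need not hold for the real data.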

Results

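Hematopoietic stem cells (Lin−Sca1+cKit+CD48−CD150+) were sorted from the marrow of 25 mice engrafted with donor marrow of 4 genotypes. The donors were labelled WT, JAK2-mutant (VF), VF without Il1b (Il1bKO) and VF without Il1r1 (Il1r1KO), and tamoxifen was given 16 weeks after transplantation. Mice were killed 2 weeks (4 libraries of each genotype) or 4 weeks (3 libraries each of VF, Il1bKO and Il1r1KO) after tamoxifen started, with no WT at 4 weeks. Library totals ran from 21990959 to 40178173 counts over 13641 genes and 4 construct sequences, and 11871 to 13491 genes were detected per library. The first principal component carried 26.2% of the variance and set 1 library, Il1bKO_4w 5, apart at a score of 224.5. That library had the most counts (40178173) but the fewest genes detected (11871, next lowest 13039). Its median r to the other libraries was 0.849, and it had 12 Il1r1 reads against 341 and 444 in its replicates. It is part of the Il1bKO values at 4 weeks and over both times unless said to be left out. Replicates of a group correlated at r = 0.85 to 0.962. The 2 times were processed as 2 batches, so comparisons between genotypes were made within time, or as the mean of the 2 within-time differences.

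The targeted genes and the constructs came first, to ask whether the libraries carried what the labels state. Il1b (ENSMUSG00000027398, chr2:129364570-129371139), the IL-1β cytokine, had 0 reads in all 7 Il1bKO libraries. It was low elsewhere: mean CPM was 2.32 (SD 5.22) in VF and 1.39 (SD 1.25) in Il1r1KO, n = 7 each, with 391 reads in VF_4w 6 alone. The other 6 VF libraries had 0, 30, 4, 6, 19 and 1 reads, and the difference of Il1bKO from VF did not pass the edgeR quasi-likelihood test (unadjusted p = 1.9e-04, Benjamini-Hochberg adjusted p = 0.0998). Il1r1 (ENSMUSG00000026072, chr1:40225080-40317257), the signalling IL-1 receptor, gave 22.2 (SD 8.14) CPM in Il1r1KO and 15.8 (SD 6.02) in VF (log2 0.43, SE 0.46, adjusted p = 0.795, edgeR). Counts over the whole gene say nothing of which exons are left, so the receptor label could not be checked. Jak2 (ENSMUSG00000024789, chr19:29251828-29313080) gave 106 (SD 12.1) CPM in VF, 93.4 (SD 24.1) in Il1bKO and 96.8 (SD 16.4) in Il1r1KO, and no comparison called it. Il1a and Il1rn, the other IL-1 ligand and the receptor antagonist, had no measurement in the table.

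The human JAK2 construct, counted in 2 parts, was at 65.8 CPM or more (part 1) and 39.1 or more (part 2) in the 21 mutant libraries, and at 0.733 and 0.182 or less in the 4 labelled WT. CreERT2 reads were 195 to 828 CPM in mutant libraries, but the libraries labelled WT had 0, 0, 1 and 0 reads although their label carries the Cre. pEGFP was present in all groups and uneven in the libraries labelled WT (998, 518, 3.03 and 49.3 CPM). Among mutants the constructs were not at equal levels. CreERT2 averaged 280 (SD 65.5) CPM in VF, 580 (SD 123) in Il1bKO and 447 (SD 80.1) in Il1r1KO, n = 7 each, which is 2.08 and 1.6 times VF. JAK2 part 1 was 115 (SD 9.85), 102 (SD 20.2) and 178 (SD 28.2) CPM, part 2 was 49.2 (SD 7.92), 67.1 (SD 17.05) and 102 (SD 10.2), and pEGFP was 489 (SD 26.8), 474 (SD 48.8) and 1010 (SD 209). An exact two-sided permutation test within time, not planned beforehand, had a smallest possible p of 0.00143. It gave that value for CreERT2 in both knockouts (log2 1.08 and 0.697 against VF, adjusted p = 0.00317). The same exact permutation p of 0.00143 held for both JAK2 parts (log2 0.593 and 1.02) and pEGFP (1.04) in Il1r1KO. In Il1bKO the permutation p was 0.0371 for part 2 (log2 0.413, adjusted p = 0.0464), 0.119 for part 1 (−0.22) and 0.686 for pEGFP (−0.057).

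**Figure D1:**
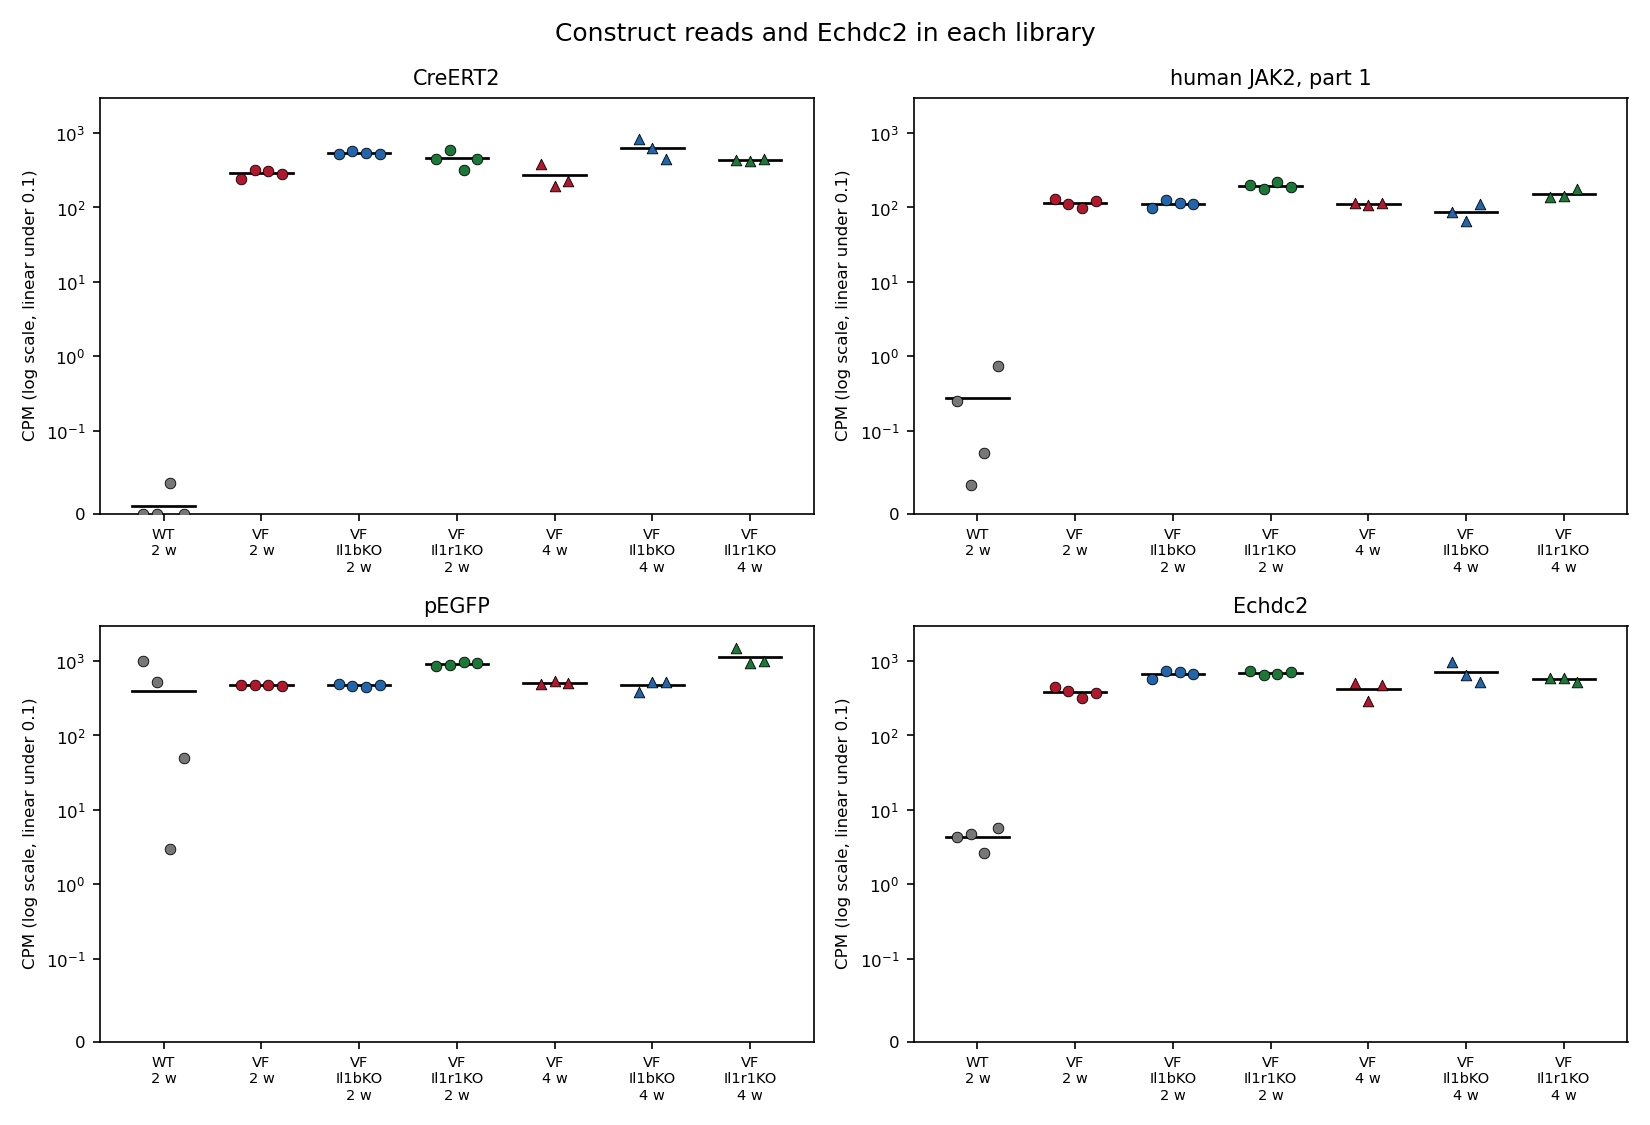
CPM of CreERT2, human JAK2 part 1, pEGFP and Echdc2 in each library by genotype (log axis, linear under 0.1; circles 2 weeks, triangles 4 weeks; line, mean). CreERT2 and Echdc2 are near 0 in the libraries labelled WT, and mean Echdc2 is 400 CPM in VF, 687 in Il1bKO and 639 in Il1r1KO.

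The effect of mutant JAK2 was asked at 2 weeks, the only time with libraries labelled WT. Echdc2 (ENSMUSG00000028601, chr4:108165437-108179308), a mitochondrial enoyl-CoA hydratase family gene, rose from 4.38 (SD 1.32) to 382 (SD 51.3) CPM, n = 4 each (log2 6.45, SE 0.24, adjusted p = 1.4e-14, edgeR quasi-likelihood, Benjamini-Hochberg). It was the only gene called of 13630, and it was called in all 19 alternatives. The next gene, Armc7, stood at 42.8 (SD 4.34) against 23.2 (SD 3.97) CPM and did not pass (log2 0.88, SE 0.17, adjusted p = 0.195), and neither did Klhl9 (−0.44), Igfbp4 (0.36), Lrmp (0.40), Scp2 (0.38) or Runx3 (1.39). The STAT5 feedback genes Socs2 (log2 0.52, SE 0.24, unadjusted p = 0.0424) and Cish (0.50, SE 0.33, unadjusted p = 0.147) and the STAT5 target kinase Pim1 (0.15, SE 0.24, unadjusted p = 0.527) did not pass either (adjusted p = 1, edgeR). Il1b itself was at log2 3.13 (SE 1.82, unadjusted p = 0.0879, edgeR), and Il1r1 at 0.14 (SE 0.60). Genes at unadjusted p < 0.05 numbered 310 against 682 expected by chance, and DESeq2 called 8 genes, limma voom 2. A count under that expected may come from a cautious test and is no evidence that genes were unchanged. In the libraries labelled WT, Mid1 was 25.7, 29.7, 1.53 and 4.07 CPM and Wdfy1 29.6, 78.9, 179 and 146, so these libraries differed among themselves in genes called elsewhere. pEGFP (998, 518, 3.03 and 49.3 CPM) parted WT_2w 1 and WT_2w 2 from WT_2w 3 and WT_2w 4 in the same way. The 4 libraries may thus not hold the same kind of cells, and the reason was not tested. Without WT_2w 3 and WT_2w 4 the count of called genes stayed at 1.

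Lists of lineage and pathway genes were then compared between VF and the libraries labelled WT. Neutrophil and monocyte genes had 31 of 35 measured members higher in VF (median log2 0.74; S100a9, a calprotectin subunit, 2.79; Csf3r, the G-CSF receptor, 0.58), and stem cell genes 33 of 41 lower (median −0.22; Mllt3 −0.69). No member of any list rose or fell by itself, also when adjusted over the list alone. Camera with a preset correlation of 0.01 called neutrophil and monocyte genes (adjusted p = 2.3e-08, adjusted p = 0.309 with an estimated correlation), a call kept without each single library. Stem cell genes (1.7e-04, adjusted p = 0.526 with an estimated correlation) lost the call without WT_2w 1 (0.174). Higher in VF were also G2 and M phase (47 of 54, median 0.19, 8.5e-06; 0.584 without WT_2w 1, adjusted p = 0.684 with an estimated correlation) and oxidative phosphorylation (67 of 76, 0.08, 2.4e-05; 0.166 without WT_2w 1, adjusted p = 0.684 with an estimated correlation). Lower were immediate early genes (26 of 29, −0.25, 0.0011, adjusted p = 0.526 with an estimated correlation) and mitochondrially encoded genes (12 of 12, −0.12, 0.0011, adjusted p = 0.594 with an estimated correlation). Ribosomal proteins were lower (60 of 76, −0.05, 9.8e-04, adjusted p = 0.754 with an estimated correlation; 0.0842 without WT_2w 2, 0.114 without WT_2w 4, 0.0535 without VF_2w 3). The type I interferon list was higher (37 of 49, 0.11, 0.00242, adjusted p = 0.684 with an estimated correlation; 0.996 without WT_2w 4, 0.199 without VF_2w 2). No camera call of the 4 comparisons of genotypes tested with lists held with an estimated correlation, and the list calls here number 12, 0 and 0 with preset correlation, estimated correlation and fry.

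The 4 further lists called higher in VF each hung on single libraries. B lineage genes (9 of 10, median 0.36, camera adjusted p = 0.0153, adjusted p = 0.592 with an estimated correlation) were lost without WT_2w 2 (0.108), WT_2w 4 (0.0671), VF_2w 2 (0.0578) or VF_2w 3 (0.0517). MYC targets (35 of 49, 0.05, 0.0261, adjusted p = 0.688 with an estimated correlation) were lost without WT_2w 1 (0.584) or VF_2w 1 (0.348). S phase genes (31 of 47, 0.06, 0.0285, adjusted p = 0.754 with an estimated correlation) turned lower without WT_2w 1 (0.00743) and were lost without VF_2w 1 (0.376). Erythroid genes (37 of 56, 0.15, 0.0354, adjusted p = 0.594 with an estimated correlation) were lost without WT_2w 1 (0.0524), WT_2w 3 (0.196), WT_2w 4 (0.14), VF_2w 1 (0.361) or VF_2w 2 (0.0952). The IL-1 pathway (camera adjusted p = 0.24), NF-kB and TNF targets (0.133), JAK-STAT targets (0.308), interferon gamma (0.861) and MHC class II (0.076) were not called. Neither were megakaryocyte (0.861), T and NK (0.689), mast, basophil and eosinophil (0.869), macrophage and dendritic (0.861), endothelial and stromal (0.438) or quiescence genes (0.249). The same held for p53 targets (0.304), glycolysis (0.563), cholesterol synthesis (0.513) and the unfolded protein response (0.446). For megakaryocyte genes the mean (0.27) was positive and the test pointed down, and for mast cell genes the median (−0.03) was negative and the test pointed up.

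Loss of Il1b in mutant cells was asked as the mean of the 2 within-time differences from VF. Il1bKO also had more CreERT2 and JAK2 part 2 reads than VF, so differences cannot be assigned to Il1b loss alone. Dock2 (ENSMUSG00000020143, chr11:34226815-34783892), a Rac activator of blood cells, fell from 233 (SD 29.4) to 128 (SD 18.9) CPM, n = 7 each (log2 −0.88, SE 0.13, adjusted p = 0.00201, edgeR quasi-likelihood). Mid1 (ENSMUSG00000035299, chrX:169685199-170005736), an X-linked ubiquitin ligase of microtubules, fell from 19.9 (SD 8.03) to 0.324 (SD 0.183) CPM (log2 −6.00, SE 0.74, adjusted p = 4.4e-04), a call lost in limma voom (0.119). It was also low in WT_2w 3 and WT_2w 4, which carry no IL-1 knockout, so its fall need not follow from loss of Il1b. Ccdc171 (ENSMUSG00000052407, chr4:83525545-83864670) fell from 44.6 (SD 10.7) to 18.9 (SD 4.35) CPM (−1.28, SE 0.20, adjusted p = 0.00305) and Tmem254c, which has near-identical copies, from 68.3 (SD 3.40) to 45.2 (SD 3.69) (−0.59, SE 0.10, adjusted p = 0.0118). Dock2, Ccdc171 and Tmem254c were called in all 23 alternatives. Ermard (−0.57, SE 0.10, adjusted p = 0.0142) was lost in 2 alternatives, among them the fit of only the compared groups (0.117). Echdc2 rose again, from 400 (SD 79.1) to 687 (SD 140) CPM (0.78, SE 0.14, adjusted p = 0.0177), a call lost without VF_2w 3 (0.0503), VF_4w 6 (0.0582) or Il1bKO_4w 5 (0.0613), in a fit of the compared groups alone (0.117) and without the 3 libraries standing apart (0.0916). In all 3 genes rose and 16 fell, with 1278 genes at unadjusted p < 0.05 against 682 expected. The 19 became 63 without Il1bKO_4w 6 and 36 without Il1bKO_4w 7.

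Further calls in Il1bKO were lost under several settings. Armc7 fell from 43.3 (SD 3.91) to 26.5 (SD 3.85) CPM (log2 −0.69, SE 0.13, adjusted p = 0.0181, edgeR), lost without VF_2w 1 (0.0593), VF_2w 3 (0.0503), VF_4w 5 (0.054), Il1bKO_2w 1 (0.0574) or Il1bKO_2w 4 (0.0545). Igfbp4, which binds insulin-like growth factors, rose from 229 (SD 20.8) to 297 (SD 79.1) CPM (0.39, SE 0.07, adjusted p = 0.0191), lost in limma voom (0.0952), in a fit of the compared groups alone (0.181) and without the 3 libraries standing apart (0.0934), and also without VF_2w 1 (0.0636), VF_4w 5 (0.0912), VF_4w 6 (0.0582), Il1bKO_2w 1 (0.0633), Il1bKO_2w 2 (0.0536) or Il1bKO_4w 5 (0.0867). The fit with the replicate block did not call Igfbp4 either. The kinase gene Hipk1 fell from 210 (SD 27.3) to 161 (SD 38.5) CPM (−0.45, SE 0.09, adjusted p = 0.0257), lost in limma voom (0.119), in a fit of the compared groups alone (0.156) and without the 3 libraries standing apart (0.106), and also without VF_2w 1 (0.0734), VF_2w 3 (0.0514), VF_2w 4 (0.0662), VF_4w 5 (0.119), VF_4w 6 (0.0585), Il1bKO_2w 1 (0.0721), Il1bKO_2w 2 (0.061), Il1bKO_2w 4 (0.0821) or Il1bKO_4w 5 (0.0878). Counting those named, 4 alternatives other than a single left-out library lost the Hipk1 call. Arhgef16 (1.27, SD 1.51, against 2.94, SD 1.35, CPM; 0 reads in Il1bKO at 4 weeks, adjusted p = 0.0177) was lost in limma voom (0.318) and without VF_4w 6 (0.0506) or Il1bKO_4w 5 (0.0776). Pim1 was at 150 (SD 32.2) against 240 (SD 85.5) CPM and did not pass (−0.69, SE 0.18, adjusted p = 0.195), nor did Socs2 (0.35, 0.572) or Cish (−0.45, 0.602).

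At 2 weeks alone Mid1 was the only gene called between Il1bKO and VF (21.2, SD 5.82, to 0.377, SD 0.139, CPM, n = 4 each; log2 −5.80, SE 0.93, edgeR adjusted p = 0.0318). It was lost without VF_2w 1 (0.104), VF_2w 2 (0.0759), VF_2w 3 (0.0955), VF_2w 4 (0.0529), Il1bKO_2w 1 (0.306), Il1bKO_2w 2 (0.347), Il1bKO_2w 3 (0.282) or Il1bKO_2w 4 (0.211), leaving 0 calls each time, and also in limma voom (0.321) and with the replicate block (0.138). At that time 186 genes had unadjusted p < 0.05. DESeq2 called 15 genes with Mid1 among them, and limma voom 11 others. At 4 weeks, n = 3 each, Igfbp4 rose from 218 (SD 25.5) to 371 (SD 54.3) CPM (0.77, SE 0.11, adjusted p = 0.00249), which limma voom (0.161) and a fit of the compared groups alone (0.938) did not call. These 2 alternatives called 0 genes at 4 weeks. Hipk1 fell from 231 (SD 32.7) to 130 (SD 9.75) CPM (−0.83, SE 0.13, adjusted p = 0.00915; 0.0796 without Il1bKO_4w 5). Serpina3f, a serpin induced by interferon, fell from 127 (SD 160) to 9.996 (SD 4.57) CPM (−3.66, SE 0.63, adjusted p = 0.0145; 33.3, 312 and 35.3 CPM in VF_4w 5, 6 and 7; 0.0668 without VF_4w 6, 0.137 without Il1bKO_4w 5). Dll4, a Notch ligand, had 0 reads in Il1bKO against 0.80, 0.98 and 4.77 CPM in VF_4w 5, 6 and 7 (adjusted p = 0.0213; 0.0526 without VF_4w 7, 0.133 without Il1bKO_4w 5). At 4 weeks 5 genes rose and 12 fell, and the 17 became 5 without Il1bKO_4w 5, 225 without Il1bKO_4w 6 and 218 without Il1bKO_4w 7. Whether the Il1b effect differed between times was tested: 2 genes passed, and the count was 0 in limma voom, with the replicate block, in a fit of the compared groups alone and without any of VF_2w 1, VF_2w 2, VF_2w 3, VF_2w 4, VF_4w 6, Il1bKO_2w 2, Il1bKO_2w 4 or Il1bKO_4w 5, 1 without Il1bKO_2w 1, 22 without Il1bKO_4w 6 and 11 without Il1bKO_4w 7.

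Il1r1KO called 23 genes against VF, 6 of them shared with Il1bKO, and those of lowest p lay on chromosome 1. Il1r1KO also had more human JAK2, CreERT2 and pEGFP reads than VF, so differences cannot be assigned to receptor loss alone. Trak2 (ENSMUSG00000026028, chr1:58900449-58973430), an adaptor for transport of mitochondria, fell from 61.5 (SD 5.21) to 30.6 (SD 6.07) CPM, n = 7 each (log2 −1.05, SE 0.10, adjusted p = 4.4e-06, edgeR quasi-likelihood). Lancl1 (ENSMUSG00000026000, chr1:67000517-67038872), a glutathione-binding protein gene, fell from 139 (SD 12.8) to 73.4 (SD 11.6) CPM (−0.92, SE 0.10, adjusted p = 4.3e-05). Wdfy1 (ENSMUSG00000073643, chr1:79702262-79776143), an endosomal adaptor of Toll-like receptor signalling, fell from 152 (SD 14.1) to 36.6 (SD 5.72) CPM (−2.06, SE 0.26, adjusted p = 2.2e-04). Acadl (ENSMUSG00000026003, chr1:66830839-66863277), the long-chain acyl-CoA dehydrogenase, fell from 200 (SD 35.9) to 123 (SD 19.9) (−0.70, SE 0.11, adjusted p = 0.00204). Mid1 fell to 0.467 (SD 0.304) CPM (−5.62, SE 0.72, 2.4e-04), Armc7 to 23.3 (SD 4.40) (−0.90, SE 0.13, 0.00111) and Ccdc171 to 20.01 (SD 9.25) (−1.26, SE 0.20, 0.00266). Mid1 was also low in WT_2w 3 and WT_2w 4, which carry no IL-1 knockout. Srp54b, of 3 near-identical copies, fell from 101 (SD 11.6) to 64.1 (SD 5.23) CPM (−0.66, SE 0.10, adjusted p = 0.00237), and Lrmda (ENSMUSG00000063458, chr14:22019712-23056085), a melanocyte differentiation gene, rose from 1.97 (SD 1.01) to 11.1 (SD 2.82) (2.48, SE 0.39, 0.00269). These 9 genes were called in all 23 alternatives. Wdfy1 and Srp54b were also lower in WT_2w 1 and WT_2w 2, which carry no IL-1 knockout, than in VF. Their fall need not follow from loss of Il1r1. In all 4 genes rose and 19 fell (1553 at unadjusted p < 0.05), and the 23 became 117 without VF_4w 6 and 15 without Il1r1KO_4w 6. The excess of lower genes was not kept in limma voom (164 higher, 156 lower) and was smaller in DESeq2 (56 and 90).

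Weaker calls in Il1r1KO were those of Strap, Igfbp4 and Trp53inp1. Beside the single libraries named below, each was also lost in 1 other alternative. Strap rose from 226 (SD 28.9) to 312 (SD 50.2) CPM (log2 0.47, SE 0.09, edgeR adjusted p = 0.0246), lost without VF_2w 3 (0.0619), VF_2w 4 (0.0515), VF_4w 5 (0.113), VF_4w 7 (0.052), Il1r1KO_2w 1 (0.0608), Il1r1KO_2w 4 (0.0611) or Il1r1KO_4w 5 (0.101). Igfbp4 rose to 293 (SD 33.1) CPM (0.38, SE 0.07, adjusted p = 0.0246), lost without VF_2w 1 (0.0622), VF_2w 4 (0.0515), VF_4w 5 (0.102), Il1r1KO_2w 1 (0.058), Il1r1KO_2w 2 (0.0536), Il1r1KO_4w 5 (0.0652) or Il1r1KO_4w 6 (0.062). Trp53inp1, a p53-induced gene, fell from 63.7 (SD 14.6) to 39.0 (SD 16.2) CPM (−0.89, SE 0.18, adjusted p = 0.0324), lost without VF_2w 2 (0.0597), VF_2w 4 (0.0964), VF_4w 5 (0.151), Il1r1KO_2w 2 (0.0614), Il1r1KO_2w 3 (0.0947), Il1r1KO_2w 4 (0.0772), Il1r1KO_4w 5 (0.125) or Il1r1KO_4w 6 (0.0984). Pim1 (149, SD 48.0, against 240, SD 85.5, CPM; −0.81, adjusted p = 0.0678), Socs2 (265, SD 59.0, against 164, SD 37.1; 0.69, 0.153) and Echdc2 (0.64, 0.0678) did not pass.

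**Figure D2:**
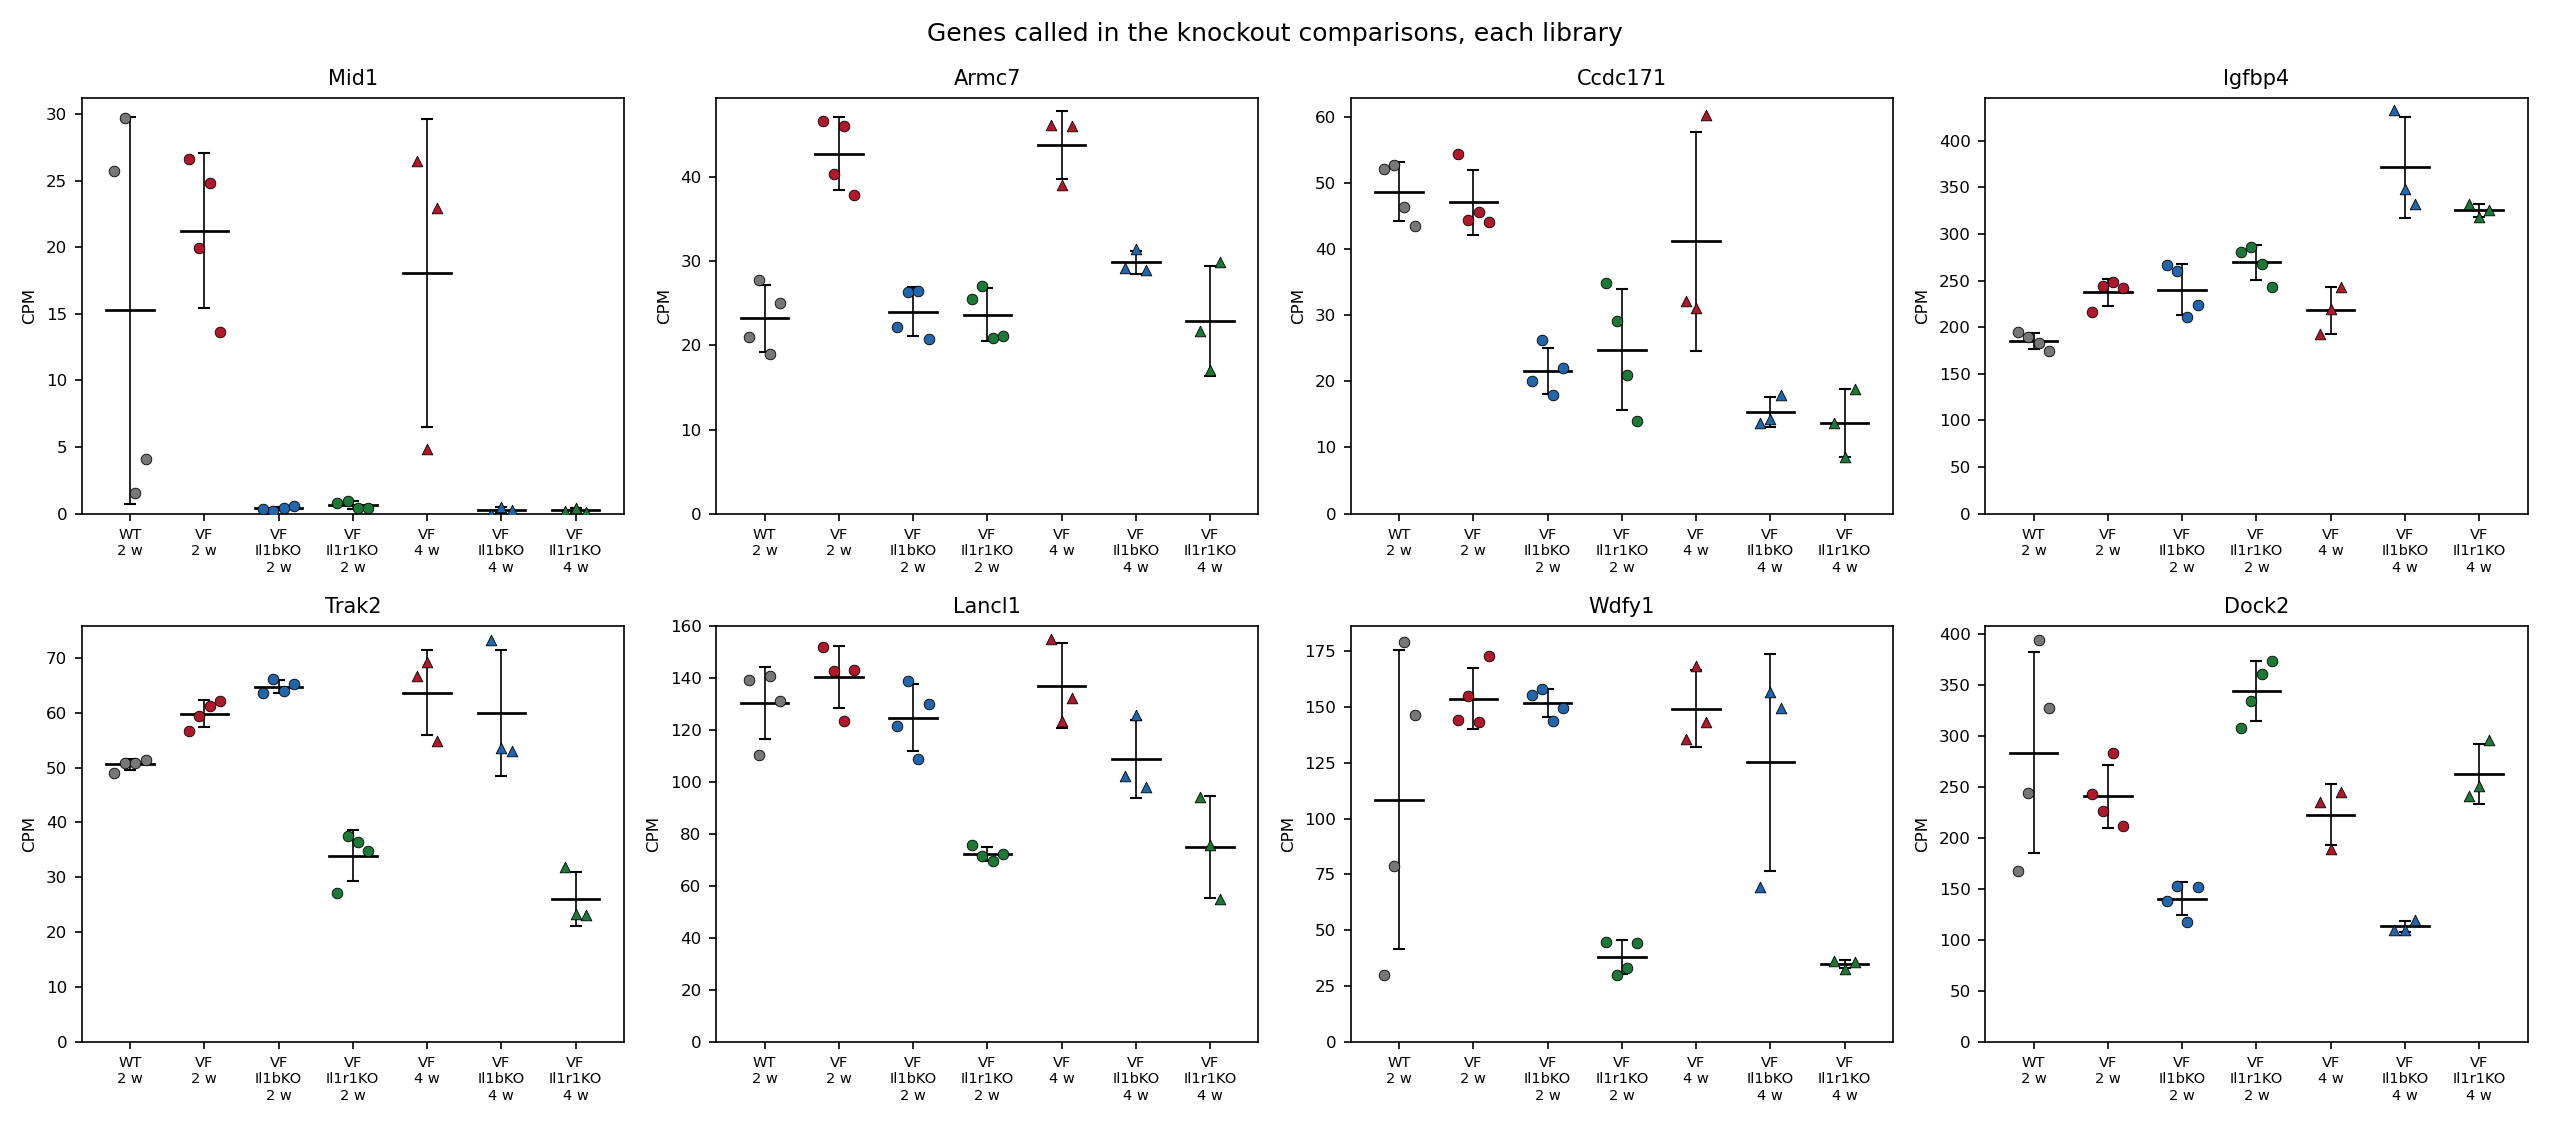
CPM of 8 genes lower or higher in the knockouts, by group (points, libraries; line, mean; bars, SD). Mid1 averages 19.9 CPM in VF against 0.324 in Il1bKO and 0.467 in Il1r1KO, and Trak2, Lancl1 and Wdfy1 are lower in Il1r1KO than in VF (Wdfy1 36.6 against 152 CPM), with Wdfy1 also low in WT_2w 1 (29.6 CPM).

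The chromosome 1 genes were also called within single times. At 2 weeks, n = 4 each, Lancl1 fell from 140 (SD 11.97) to 72.2 (SD 2.58) CPM (log2 −0.96, SE 0.13, edgeR adjusted p = 0.00373) and was called in all 18 alternatives. Trak2 fell too (−0.82, SE 0.13, adjusted p = 0.0149), a call lost without VF_2w 2 (0.0609), VF_2w 3 (0.0508), VF_2w 4 (0.0625), Il1r1KO_2w 1 (0.0832) or Il1r1KO_2w 4 (0.0721). The 2-week calls (1 higher, 6 lower; 430 at unadjusted p < 0.05) became 2 without VF_2w 1, Il1r1KO_2w 2 or Il1r1KO_2w 3, and 1 without VF_2w 2, VF_2w 3, VF_2w 4, Il1r1KO_2w 1 or Il1r1KO_2w 4. At 4 weeks, n = 3 each, Trak2 fell from 63.7 (SD 7.76) to 26.1 (SD 4.96) CPM (−1.29, SE 0.15, adjusted p = 2.3e-04), and was lost only in a fit of the compared groups alone (0.485). Treml2, a receptor of myeloid and B cells, fell from 152 (SD 12.2) to 87.6 (SD 2.65) CPM (−0.79, SE 0.13, adjusted p = 0.0238), lost without VF_4w 5 (0.0745), Il1r1KO_4w 6 (0.105) or Il1r1KO_4w 7 (0.0615). The 4-week calls (2 higher, 18 lower) became 2 without VF_4w 5, 139 without VF_4w 6, 5 without Il1r1KO_4w 5, 1 without Il1r1KO_4w 6 and 5 without Il1r1KO_4w 7. Limma voom called 204 higher and 199 lower, DESeq2 76 and 155, and a fit of the compared groups alone 1, lower. A difference of the receptor effect between times was tested and 0 genes passed in edgeR (725 at unadjusted p < 0.05; DESeq2 called 22 genes, limma voom 5). The lowest there, Sec63 (−0.76, SE 0.14, adjusted p = 0.232), did not pass, and 2 genes were called without VF_4w 6 or without Il1r1KO_4w 7.

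Genes near the knocked-out loci were tested, because a knockout allele can bring flanking sequence of the strain it was made in. Within 20 Mb of Il1r1, 2 of 163 tested genes were called (Trak2 18.6 Mb and Mpp4 18.8 Mb away) against 21 of 13448 elsewhere (odds ratio 7.94, two-sided Fisher exact p = 0.0306). Within 10 or 5 Mb none was called (Fisher exact p = 1). The 20 Mb result was lost without VF_2w 1 (0.214), VF_2w 2 (0.195), VF_2w 3 (0.214), VF_2w 4 (0.185), VF_4w 5 (0.185), VF_4w 6 (0.165), VF_4w 7 (0.26), Il1r1KO_2w 1 (0.195), Il1r1KO_2w 2 (0.233), Il1r1KO_2w 3 (0.214), Il1r1KO_4w 5 (0.175) or Il1r1KO_4w 6 (0.165). Of the 23 genes called in Il1r1KO, 5 lay on chromosome 1, all lower, with 1.31 expected (exact test, p = 0.00843, 0.27 after Bonferroni over chromosomes): Trak2, Mpp4, Acadl (26.5 Mb away), Lancl1 (26.7 Mb) and Wdfy1 (39.4 Mb). At 2 weeks chromosome 1 held 4 of the 7 calls (0.399 expected, exact p = 3.2e-04, 0.0102 after Bonferroni). Wdfy1 is in both counts, although it was also lower in WT_2w 1 and WT_2w 2 than in VF. Over both times chromosome 12 held 4 (0.767 expected, exact p = 0.0065, 0.208 after Bonferroni) and chromosome 4 held 5 (1.43 expected, 0.0121 and 0.386). Within 20 Mb of Il1b, 1 of 252 genes was called in Il1bKO against 18 of 13359 (Fisher exact p = 0.299), and chromosome 2 held 3 of 19 calls (Dll4, Gm14403 and Gm14325; 1.52 expected, p = 0.192).

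Lists of cycling and respiration genes were higher in Il1r1KO, whose human JAK2 and other construct reads also exceeded those of VF. All 47 S phase genes were higher in Il1r1KO than in VF (median log2 0.32; 0 passed among all genes, 1 rose adjusted over the list alone; camera adjusted p = 3.4e-14, adjusted p = 0.478 with an estimated correlation). G2 and M phase genes followed (52 of 54, 0.28, 7.0e-09, adjusted p = 0.628 with an estimated correlation), as did oxidative phosphorylation (74 of 76, 0.15, 3.4e-14, adjusted p = 0.494 with an estimated correlation). MYC targets (41 of 49, 0.09, 0.00166, adjusted p = 0.659 with an estimated correlation) were lost without VF_4w 5 (0.0669). Endothelial and stromal genes (10 of 13, 0.52, 0.0171, adjusted p = 0.402 with an estimated correlation) were lost without VF_4w 6 (0.0987). NF-kB and TNF targets, downstream of the receptor, were lower (30 of 41, median −0.22, 1 fell adjusted over the list alone; the chemokine gene Ccl4 −1.17, the kinase gene Map3k8 −0.85, against Nfkb1 0.23). Their camera adjusted p was 3.8e-04 (adjusted p = 0.0603 with an estimated correlation), and they were the only list called by fry (0.007). The IL-1 pathway list was lower (11 of 17, −0.21, camera 0.0231, adjusted p = 0.478 with an estimated correlation), with Il18rap, Il18r1 and Il1r2 lower when adjusted over the list alone (−1.28, −3.93 and −3.49). These 3 genes are neighbours of Il1r1 itself, 0.198, 0.148 and 0.0999 Mb away on chromosome 1, so an effect of the allele on its surroundings was not separated from a pathway change. The call of the list was lost without VF_4w 5 (0.0609), VF_4w 6 (0.0987) or Il1r1KO_4w 6 (0.126). Mast cell genes (9 of 10 lower, −0.76, 0.0188, adjusted p = 0.316 with an estimated correlation) were lost without VF_4w 7 (0.103). In all 11 lists were called, 7 without VF_4w 6. JAK-STAT targets (0.265) and p53 targets (0.566; 4 rose and 1 fell adjusted over the list alone) were not called.

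Interferon genes were lower in both knockouts, and this came from 1 library. Of the 42 interferon gamma genes measured, 39 were lower in Il1bKO (median log2 −0.38; Gbp4, a guanylate-binding protein gene, −2.03; 8 fell adjusted over the list alone) and 39 in Il1r1KO (−0.43; 4 fell adjusted over the list alone). The MHC class II list was lower in Il1bKO (10 of 11, −0.56, 2 fell adjusted over the list alone; H2-Aa −1.05; Ciita, its transactivator, −1.08) and Il1r1KO (11 of 11, −0.69). Camera adjusted p for interferon gamma was 8.3e-05 in Il1bKO (adjusted p = 0.832 with an estimated correlation) and 4.1e-06 in Il1r1KO (adjusted p = 0.628 with an estimated correlation). Without VF_4w 6 these became 0.895 and 0.976. MHC class II gave 0.0189 and 0.00132 (adjusted p = 0.832 and adjusted p = 0.478 with an estimated correlation). It was lost without VF_4w 6 in both (0.568 and 0.319), and in Il1bKO also without VF_2w 3 (0.0744), Il1bKO_2w 4 (0.0717), Il1bKO_4w 6 (0.159) or Il1bKO_4w 7 (0.0951). In VF_4w 6 the summed interferon gamma genes reached 33300 CPM, against 12700 to 17200 in the other 24 libraries. MHC class II genes reached 3080 CPM there, against 350 to 1040.

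**Figure D3:**
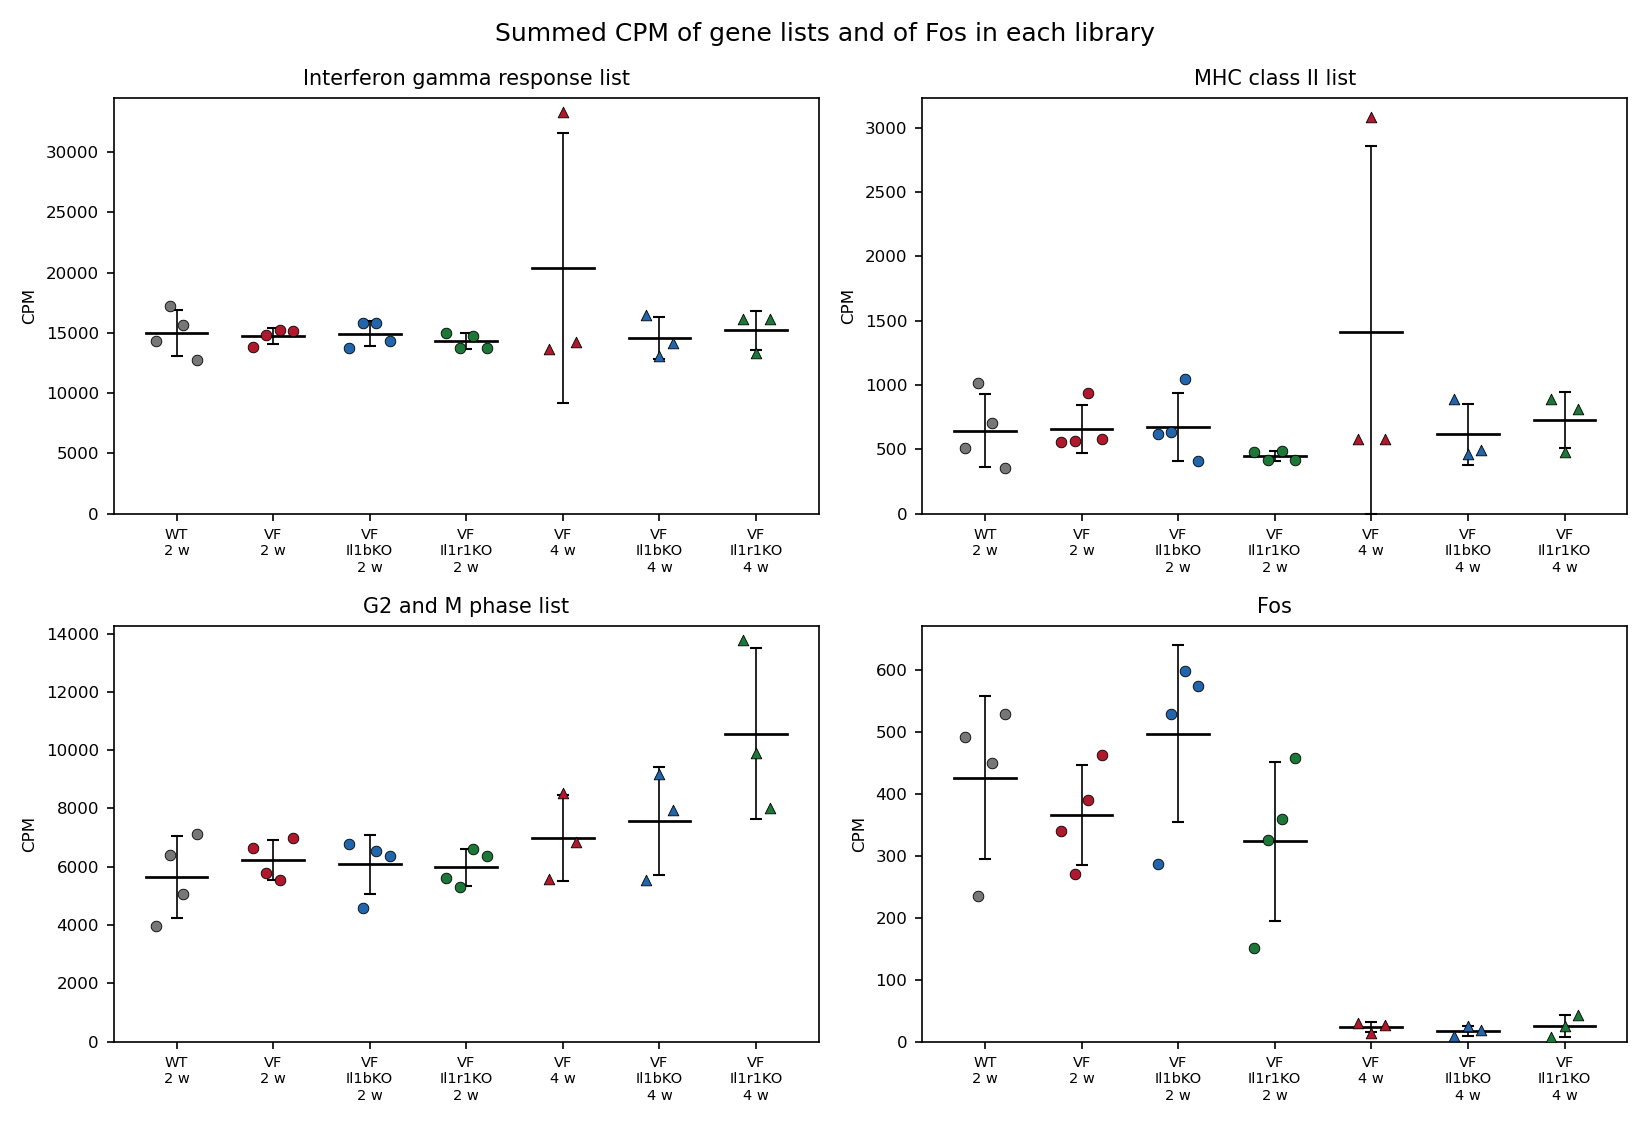
Summed CPM of the interferon gamma, MHC class II and G2 and M phase lists and CPM of Fos by group (points, libraries; line, mean; bars, SD). VF_4w 6 reaches 33300 CPM in the interferon gamma list, and Fos falls from 366 to 23.7 CPM in VF between 2 and 4 weeks.

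The other lists called in Il1bKO against VF were megakaryocyte, ribosomal, S phase, type I interferon and cholesterol synthesis genes. Megakaryocyte genes were lower (34 of 38, median log2 −0.38, camera adjusted p = 0.00292, adjusted p = 0.832 with an estimated correlation; 0.568 without VF_4w 6). S phase genes were higher (37 of 47, 0.14, 0.00148, adjusted p = 0.832 with an estimated correlation; 0.182 without VF_4w 5, 0.159 without Il1bKO_4w 6, 0.0572 without Il1bKO_4w 7). Ribosomal proteins were lower (66 of 76, −0.10, 5.2e-04, adjusted p = 0.832 with an estimated correlation; 0.0951 without Il1bKO_4w 7). Type I interferon genes were lower (43 of 49, −0.18, 0.021, adjusted p = 0.832 with an estimated correlation), lost without VF_2w 2 (0.138), VF_4w 6 (0.568), Il1bKO_2w 1 (0.0837), Il1bKO_4w 6 (0.409) or Il1bKO_4w 7 (0.0951). In Il1r1KO the same list was lower (41 of 49, −0.26, 3.0e-04, adjusted p = 0.669 with an estimated correlation; 0.976 without VF_4w 6). Cholesterol synthesis genes were lower in Il1bKO (26 of 33, −0.13, 0.0255, adjusted p = 0.832 with an estimated correlation), lost without VF_2w 3 (0.0647), VF_2w 4 (0.0761), VF_4w 6 (0.612), Il1bKO_2w 4 (0.0717), Il1bKO_4w 5 (0.0843) or Il1bKO_4w 7 (0.0951). NF-kB targets (0.421), the IL-1 pathway (0.391; Il1b alone fell adjusted over the list) and JAK-STAT targets (0.933; 3 fell adjusted over the list alone) were not called. The 7 list calls became 3 without VF_4w 6, 4 without Il1bKO_4w 6 and 2 without Il1bKO_4w 7.

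Ligand and receptor loss were compared directly, mean of times, n = 7 each. Levels of the constructs also differed between these genotypes. Trak2 was higher in Il1bKO (62.7, SD 7.20, against 30.6, SD 6.07, CPM; log2 1.07, SE 0.10, edgeR adjusted p = 3.4e-06) and so was Wdfy1 (140, SD 31.8, against 36.6, SD 5.72; 1.92, SE 0.26, 6.5e-04). Dock2 was lower in Il1bKO (128, SD 18.9, against 309, SD 51.1, CPM; −1.26, SE 0.13, 1.6e-05), as were Strap (202, SD 29.4, against 312, SD 50.2; −0.63, SE 0.09, 0.00107) and Lrmda (2.23, SD 0.81, against 11.1, SD 2.82; −2.26, SE 0.39, 0.00659). Chrnb1, a muscle acetylcholine receptor subunit, was higher in Il1bKO (38.4, SD 13.5, against 17.5, SD 9.47; 1.44, SE 0.22, 0.00191), as was Fam49a (70.6, SD 11.2, against 37.7, SD 6.13; 0.91, SE 0.14, 0.00212). These 7 genes were called in all 23 alternatives. In all 15 genes were higher and 9 lower (1917 at unadjusted p < 0.05), and the 24 became 124 without Il1bKO_4w 6 and 43 without Il1r1KO_4w 7. Oxidative phosphorylation was lower in Il1bKO (74 of 76, median −0.16, camera adjusted p = 2.4e-08, adjusted p = 0.786 with an estimated correlation), as were MYC targets (44 of 49, −0.14, 2.0e-04, adjusted p = 0.786 with an estimated correlation) and S phase genes (43 of 47, −0.18, 4.2e-04, adjusted p = 0.806 with an estimated correlation). G2 and M phase genes (49 of 54 lower, −0.29, 2.0e-04, adjusted p = 0.806 with an estimated correlation) were lost without Il1r1KO_4w 5 (0.0557). Megakaryocyte genes (31 of 38 lower, −0.48, 0.00805, adjusted p = 0.786 with an estimated correlation) were lost without Il1bKO_4w 6 (0.0518). Ribosomal proteins (69 of 76 lower, −0.11, 4.7e-04, adjusted p = 0.919 with an estimated correlation) were lost without Il1bKO_4w 6 (0.0502), Il1bKO_4w 7 (0.0518) or Il1r1KO_4w 5 (0.908). Erythroid genes (42 of 56 lower, −0.23, 0.0404, adjusted p = 0.786 with an estimated correlation) were lost without Il1bKO_2w 1 (0.0856) or Il1r1KO_4w 7 (0.437), among others. NF-kB and TNF targets were the only list called higher in Il1bKO (23 of 41, median 0.11, 3 higher adjusted over the list alone; camera adjusted p = 0.045, adjusted p = 0.786 with an estimated correlation), lost without Il1r1KO_4w 5 (0.126) and 7 other single libraries. The 8 list calls became 4 without Il1bKO_4w 6, 5 without Il1bKO_4w 7 and 5 without Il1r1KO_4w 5.

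Both knockouts shared 6 called genes against VF. Hipk1, Mid1, Armc7, Ccdc171 and the copy gene Gm21748 were lower in both, and Igfbp4 was higher in both. Gm21748 lies on chromosome Y and Mid1 on chromosome X. Chromosome Y held 1 call in each comparison (0.00698 and 0.00845 expected, Fisher exact p = 0.00695 and 0.00841, 0.222 and 0.269 after Bonferroni). Whether the sex of the mice differed between groups was not tested. Both comparisons use the same VF libraries, and simulations of unchanged groups with shared VF libraries called 0 genes in both on average. The simulations draw only variation between libraries, so they cannot separate IL-1 loss from another difference of VF from both knockouts. Across all tested genes the 2 log2 fold changes correlated at r = 0.426, against 0.504 (0.473 to 0.52) in 12 simulations of unchanged groups with shared VF libraries. Their covariance was 0.193, against 0.0852 simulated. With the VF libraries of 2 weeks divided so that none was shared, r was 0.0978 (0.0449 to 0.148 over 6 such divisions) and the covariance 0.0303, against r = 0.492 and 0.113 with all shared.

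Whether the knockouts move back genes that differ between VF and the libraries labelled WT was asked with libraries that the comparisons do not share. Echdc2, the only gene called between VF and the libraries labelled WT, moved up in both knockouts and not back. The libraries labelled WT also had almost no CreERT2 reads, so Echdc2 is not shown to depend on mutant JAK2. Of the 52 genes with p < 0.01 in VF against the libraries labelled WT, 34 (65.4%) moved in the same direction in Il1bKO at 4 weeks (r = 0.0479, Spearman 0.12) and 30 (57.7%) in Il1r1KO (r = −0.014, Spearman 0.136). VF against the libraries labelled WT gave 310 genes at unadjusted p < 0.05, fewer than the 682 expected by chance. The 52 can therefore not be taken as genes that depend on mutant JAK2. So low a count may come from a cautious test, so it is no evidence that such genes are lacking. With 2-week libraries only, calls against the libraries labelled WT rose from 6 to 12 in Il1bKO and from 8 to 25 in Il1r1KO. They stayed at 1 in VF. At 2 weeks, where VF libraries are shared, r was −0.482 and −0.435, against −0.508 and −0.498 in simulations of unchanged groups.

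Against the libraries labelled WT at 2 weeks, n = 4 each, both knockouts called the same 4 genes beside Mid1. Echdc2 was higher at 670 (SD 71.6) CPM in Il1bKO and 692 (SD 37.7) in Il1r1KO (log2 7.26 and 7.30, SE 0.25 each, edgeR adjusted p = 2.2e-15 and 2.0e-15). Klhl9, a ubiquitin ligase adaptor, fell from 132 (SD 5.33) to 82.5 (SD 3.58) and 69.1 (SD 9.52) CPM (−0.67 and −0.93, adjusted p = 0.0137 and 1.8e-04). In Il1r1KO that call was kept in all 19 alternatives. In Il1bKO it was lost without WT_2w 2 (0.0512), WT_2w 3 (0.073), Il1bKO_2w 1 (0.0695), Il1bKO_2w 2 (0.084) or Il1bKO_2w 3 (0.114). The Il1bKO call of Klhl9 was also lost in 2 other alternatives, among them the replicate block. Scp2, sterol carrier protein 2, rose from 198 (SD 15.6) to 320 (SD 25.96) and 320 (SD 26.9) CPM (0.69 in both, adjusted p = 0.00902 and 0.00567). In Il1bKO this was lost without WT_2w 2 (0.0512) or Il1bKO_2w 2 (0.0636). In Il1r1KO the Scp2 call was lost in a fit of the compared groups alone (edgeR adjusted p = 0.0614). Of the Il1bKO calls (3 higher, 3 lower; 422 at unadjusted p < 0.05), 2 were left without WT_2w 2, 3 without WT_2w 3, 2 without Il1bKO_2w 1, 1 without Il1bKO_2w 2 and 2 without Il1bKO_2w 3. The Il1r1KO calls (4 higher, 4 lower; 815 at unadjusted p < 0.05) became 4 without WT_2w 2 and 5 without Il1r1KO_2w 1, Il1r1KO_2w 2 or Il1r1KO_2w 3.

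Tal1, a transcription factor of blood stem cells, rose in both knockouts against the libraries labelled WT, from 60.5 (SD 2.69) to 96.5 (SD 7.36) CPM in Il1bKO and 94.1 (SD 5.08) in Il1r1KO (log2 0.67 and 0.64, SE 0.11 each, n = 4, edgeR adjusted p = 0.0137 and 0.0224). In both knockouts the Tal1 call was lost without WT_2w 3 and WT_2w 4 together, and in Il1r1KO also in a fit of the compared groups alone. In Il1bKO the call was also lost without WT_2w 1 (0.0511), WT_2w 2 (0.0713), WT_2w 3 (0.0615), WT_2w 4 (0.0663), Il1bKO_2w 1 (0.092), Il1bKO_2w 2 (0.084) or Il1bKO_2w 3 (0.0961). In Il1r1KO it was lost without WT_2w 1 (0.0547), WT_2w 2 (0.0833), WT_2w 3 (0.0676), WT_2w 4 (0.0764), Il1r1KO_2w 1 (0.056), Il1r1KO_2w 2 (0.068), Il1r1KO_2w 3 (0.131) or Il1r1KO_2w 4 (0.0772). Lancl1 fell in Il1r1KO from 130 (SD 13.9) to 72.2 (SD 2.58) CPM (−0.85, SE 0.13, adjusted p = 0.00567), and was kept without each single library but lost in 1 other alternative. Echdc2, Scp2 (chr4:108043839-108144998), Tal1 (chr4:115056426-115071755) and Klhl9 (chr4:88718292-88722465) all lie on chromosome 4. That chromosome held 4 of the 6 genes called in Il1bKO (0.373 expected, two-sided Fisher exact p = 2.0e-04, 0.00642 after Bonferroni over chromosomes) and 4 of the 8 in Il1r1KO (0.498 expected, 8.5e-04 and 0.0271). Genes at unadjusted p < 0.05 were not clearly denser within 20 Mb of Echdc2 (13 of 242 against 408 of 13369 in Il1bKO, Fisher exact p = 0.0566, and 20 against 793 in Il1r1KO, p = 0.131). Scp2, Tal1 and Klhl9 all lie within those 20 Mb. Called genes there were not tested as they were near Il1r1, so this does not argue against clustering of calls around Echdc2.

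Between 2 and 4 weeks immediate early genes fell in all 3 mutant genotypes, a comparison in which time and processing batch cannot be told apart. Fos, an AP-1 subunit, fell in VF from 366 (SD 80.8) to 23.7 (SD 8.27) CPM, n = 4 and 3 (log2 −3.95, SE 0.52, edgeR adjusted p = 0.00103), and in Il1bKO from 497 (SD 143) to 17.1 (SD 7.68) (−4.87, SE 0.54, 9.0e-05) and Il1r1KO from 323 (SD 128) to 25.2 (SD 18.0) (−3.68, SE 0.51, 0.00174). Dusp1, a MAP kinase phosphatase gene, fell in VF from 273 (SD 62.8) to 63.9 (SD 19.9) CPM (−2.09, SE 0.28, 0.00103). Zfp36, an mRNA decay factor, fell in VF from 328 (SD 40.2) to 88.7 (SD 8.26) CPM (−1.89, SE 0.28, 0.00336; lost without VF_4w 6, 0.0694). The immediate early list held its camera call with an estimated correlation in VF (median −0.55, 3 fell, 10 adjusted over the list alone; 2.7e-11, adjusted p = 0.0303 with an estimated correlation), Il1bKO (−1.13, 13 fell, 16 alone; 5.5e-11, adjusted p = 0.0352) and Il1r1KO (−1.26, 12 fell, 19 alone; 3.4e-13, adjusted p = 0.0163). VF called 3 genes, all lower, in edgeR (1156 at unadjusted p < 0.05), and 8 without VF_4w 5. DESeq2 called 13 higher and 33 lower there, and limma voom 86 and 69.

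The knockouts were compared between times as well, with the same batch limit. Fewer genes were called in VF than in Il1bKO by edgeR (3 and 102), but more by limma voom (155 and 108) and in fits of the compared groups alone (6 and 4). In Il1r1KO 227 genes rose and 108 fell (174 and 106 with RLE factors, 120 and 104 with upper-quartile factors). The excess of rising genes was not stable: 22 rose and 23 fell without Il1r1KO_2w 1, 38 and 54 without Il1r1KO_2w 2, 6 and 26 without Il1r1KO_2w 4, and 0 and 10 without Il1r1KO_4w 5. Tmem256 (log2 0.70, SE 0.12, edgeR adjusted p = 0.0127) and Rnaseh2c, a ribonuclease H2 subunit (0.67, SE 0.12, 0.0127), rose, and both were lost without Il1r1KO_4w 5 (0.137 and 0.122). All 54 G2 and M phase genes were higher at 4 weeks (median 0.95; 16 rose, 50 adjusted over the list alone; camera 2.7e-26, adjusted p = 0.151 with an estimated correlation), and 75 of 76 oxidative phosphorylation genes (0.48; 26 rose, 68 alone; 2.9e-33, adjusted p = 0.12). Stem cell genes were lower in Il1r1KO (−0.38; 3 fell, 8 alone; 2.7e-06, adjusted p = 0.12). The 335 calls became 45 without Il1r1KO_2w 1, 92 without Il1r1KO_2w 2, 74 without Il1r1KO_2w 3, 32 without Il1r1KO_2w 4, 10 without Il1r1KO_4w 5 and 827 without Il1r1KO_4w 7. In Il1bKO 41 genes rose and 61 fell by edgeR, a balance that limma voom turned round (73 higher, 35 lower). Igfbp4 rose there from 240 (SD 27.2) to 371 (SD 54.3) CPM (0.63, SE 0.10, 0.00586; lost without Il1bKO_4w 5, 0.0545), and Klf6 fell from 215 (SD 60.1) to 69.5 (SD 4.199) (−1.63, SE 0.27, 0.00589; lost without Il1bKO_4w 5, 0.0541). The 102 calls became 19 without Il1bKO_2w 2, 37 without Il1bKO_2w 3, 15 without Il1bKO_2w 4, 8 without Il1bKO_4w 5, 392 without Il1bKO_4w 6 and 516 without Il1bKO_4w 7.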

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

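The count of calls by chromosome, the tests of the 3 patterns weighed here other than the locus test, and the split counts of VF against the libraries labelled WT, of Il1bKO against VF over both times and of Il1bKO by time, were chosen only after the result was seen.

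Some single libraries stood apart from an otherwise tight group, by a ratio of gap to range. Ccdc171 was 54.3 CPM in VF_2w 1 against 44 to 45.6 in the others (ratio 0.85), Strap 193 in VF_2w 3 against 212 to 215 (0.858), and Purb 75.9 in Il1r1KO_2w 2 against 101 to 106 (0.843). Hipk1 was 193 CPM in Il1r1KO_2w 1 against 143 to 147 (0.917), and CreERT2 568 in Il1bKO_2w 2 against 527 to 532 (0.883). Il1b had 0.139 CPM in WT_2w 2 and CreERT2 0.0365 in WT_2w 3, each against 0 in the others (ratio 1). These were 7 of 127 groups, against 6.35 that such a test picks out by chance, about 1 in 20. For 2 genes the effect of Il1b loss passed a test of difference between times in edgeR, but 0 passed in limma voom, with the replicate block, in a fit of the compared groups alone or without the 3 libraries standing apart, and 23 of 100 splits called as many. Gm4841, an interferon-inducible GTPase family gene, was at 15.6 (SD 11.9) CPM in VF and 1.07 (SD 0.232) in Il1bKO at 4 weeks (4-week minus 2-week difference −3.68, SE 0.60, edgeR adjusted p = 0.0375). 1810020O05Rik had 0 reads in Il1bKO at 4 weeks (−8.38, adjusted p = 0.0391, a fitted value that depends on the prior count; at least 81.8-fold lower at 4 weeks). Construct reads divided the libraries fully: the lowest mutant library had 65.8 CPM of JAK2 part 1, 39.1 of part 2 and 195 of CreERT2, against 0.733, 0.182 and 0.0365 at most in those labelled WT.

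Echdc2 was high in every mutant library and at 4.38 (SD 1.32) CPM in those labelled WT. Residual cells without pEGFP do not explain the low Echdc2 in WT_2w 1 and WT_2w 2. Their pEGFP (998 and 518 CPM) was above the VF mean of 489, and Echdc2 there reached 0.015 of the lowest VF library. Both had 0 CreERT2 reads, so pEGFP does not show that their cells came from the labelled donor. Other cells without the Cre are not excluded. The rule for CreERT2 was set after these levels were known and used a lower ratio than that for human JAK2. It therefore cannot favour CreERT2 over human JAK2, whose part 2 was also higher in both knockouts. By that rule the higher Echdc2 fits a tie to the CreERT2 transgene, whose level was at least 1.6 times VF in both knockouts, with Echdc2 at 1.72 and 1.6 times VF (exact permutation p = 0.00143 each, n = 7). A chromosome 4 segment carried with the transgene (Fisher p = 0.27 for neighbours within 20 Mb, though chromosome 4 held 4 of 6 and 4 of 8 calls of the knockouts against the libraries labelled WT) and the level of human JAK2 (part 1 at 0.886 and 1.55 times VF in Il1bKO and Il1r1KO, part 2 at 1.36 times VF in Il1bKO and at 102 against 49.2 CPM in Il1r1KO) cannot be told apart from it here. The called genes Scp2, Tal1 and Klhl9 lie within those 20 Mb, and the test of neighbours did not use called genes. Within genotypes r of Echdc2 with CreERT2 was 0.897 in Il1bKO (two-sided permutation p = 0.0161, n = 7; Spearman 0.714, p = 0.0881), 0.373 in VF (p = 0.407) and 0.0634 in Il1r1KO (p = 0.925), and without the 2 farthest libraries 0.828, −0.85 and 0.533, so no common relation was seen there.

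The lower chromosome 1 genes in Il1r1KO fit sequence of another strain around the Il1r1 allele, with Fisher exact p = 0.0306 for called genes within 20 Mb. The p was 1 within 10 and 5 Mb and 0.0927 without the 3 libraries standing apart, while Il1r2, Il18r1 and Il18rap, all within 0.2 Mb, were lower without passing (edgeR adjusted p = 0.26, 0.257 and 0.11). Over both times calls were as dense on chromosome 12 (exact p = 0.0065) as on chromosome 1 (0.00843) and neither passed Bonferroni, but at 2 weeks chromosome 1 held 4 of 7 calls (3.2e-04, 0.0102 after Bonferroni). An effect of receptor loss on these genes stays untested and open. Without any of 12 of the 14 libraries p was 0.165 to 0.26.

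Lower interferon gamma and MHC class II genes in both knockouts fit 1 library, VF_4w 6. Without it the median log2 fold change of the interferon gamma list at 4 weeks was 0.0177 in Il1bKO and 0.0639 in Il1r1KO, against −0.938 and −0.989 with it. B lineage genes were at 0.84 and macrophage and dendritic genes at 0.616 of the other VF libraries of 4 weeks, so neither list was raised there. The 0.616 rests on VF_4w 5 (373 CPM), since VF_4w 7 had 171 CPM and VF_4w 6 had 167. T and NK genes were at 1.44 times and megakaryocyte genes at 2.03 times the other VF libraries of 4 weeks. Sums of lists cannot exclude cells of another lineage with MHC class II as the source.

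Gene counts were compared with those of splits of the libraries that mix the groups. With 35 splits of which 1 is the real one, the real count was the only one as large for VF against the libraries labelled WT (1 gene; highest other 0), Il1bKO at 2 weeks (1; 0), Il1r1KO at 2 weeks (7; 0), Il1bKO against the libraries labelled WT (6; 0) and Il1r1KO against them (8; 2). For Il1bKO at 2 weeks the 1 gene was lost without any one of the 8 libraries, so chance is not called excluded there. The real count was also the only one as large with time for VF (3; 0), Il1bKO (102; 1) and Il1r1KO (335; 25). With 100 splits it held for Il1bKO (19; 5) and Il1r1KO (23; 5) over both times. Between the knockouts 2 of 100 splits reached the real 24, and the other called 135, several times as many. That split kept most Il1bKO libraries together, and what it reflects was not tested. Chance is not excluded for the difference of the Il1b effect between times (2 genes; highest other 5; 23 of 100 splits as large) or of the receptor effect (0; 2; 100 of 100). The 4-week comparisons have 10 splits, too few for a share under 0.05 (Il1bKO 17, highest other 7, 1 as large; Il1r1KO 20, highest other 28, 2 as large). For lists chance is not excluded in VF against the libraries labelled WT (12 lists; highest other 14; 6 of 35), Il1bKO (7; 12; 56 of 100), Il1r1KO (11; 17; 31 of 100) or between the knockouts (8; 12; 13 of 100).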

How the results depend on the processing

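The fits without 3 libraries standing apart, without 2 libraries labelled WT and with 2-week libraries only were chosen only after the result was seen. Gene counts below are, where given, for VF against the libraries labelled WT, Il1bKO against VF (both times, 2 weeks, 4 weeks), Il1r1KO against VF (same order), between knockouts, each knockout against the libraries labelled WT, and with time. DESeq2 called 8; 100, 15, 375; 146, 20, 231; 166; 24 and 46; and with time 46 (VF), 607 (Il1bKO) and 929 (Il1r1KO), with 51 and 22 for time dependence. Limma voom called 2; 11 at 2 weeks and 0 at 4 weeks in Il1bKO; 320, 22 and 403 in Il1r1KO; 12 and 25 against the libraries labelled WT; 155 (VF), 108 (Il1bKO) and 510 (Il1r1KO) with time; 0 and 5 for time dependence; the Il1r1 locus p was 0.287. With only the compared groups in the fit the counts were 3; 7 and 0 for Il1bKO at 2 and 4 weeks; 39, 11 and 1 for Il1r1KO; 3 for Il1r1KO against the libraries labelled WT; 6, 4 and 39 with time; 0 for time dependence of Il1bKO; locus p 0.377. With the replicate block Il1bKO gave 0 at 2 weeks and 7 at 4 weeks, Il1r1KO 2 and 5, the knockouts against the libraries labelled WT 3 and 5, time dependence of Il1bKO 0, and locus p 0.214. Without the 3 libraries standing apart Il1r1KO gave 296 over both times and 398 at 4 weeks, the knockouts against the libraries labelled WT 15 and 21, VF with time 14, Il1r1KO with time 119 (23 higher, 96 lower), time dependence 0 and 32, Il1bKO lists 3 and locus p 0.0927. With 2-week libraries only Il1r1KO gave 12 at 2 weeks and the knockouts against the libraries labelled WT 12 and 25. The strict filter gave 5 for VF with time, 1 for time dependence of Il1bKO and locus p 0.211. List calls with an estimated correlation were 0, 0, 0 and 0, and with fry 0, 0, 1 and 0. Locus windows of 10 and 5 Mb gave p = 1, divided VF libraries r = 0.1, and genes at p < 0.01 a same-sign share of 65.4% and 57.7% (100% for the 1 called gene). Without WT_2w replicate 1 the S phase list turned lower in VF (adjusted p = 0.00743), with 1.93e-05 to 0.376 without other libraries. Leaving out single libraries gave 1 to 1 genes for VF against the libraries labelled WT; 13 to 63, 0 to 0 and 5 to 225 for Il1bKO; 15 to 117, 1 to 2 and 1 to 139 for Il1r1KO; 23 to 124 between knockouts; 1 to 6 and 4 to 12 against the libraries labelled WT; 2 to 8, 8 to 516 and 10 to 827 with time; 0 to 22 and 0 to 2 for time dependence. Lists ran 8 to 13, 2 to 9, 7 to 13 and 4 to 9, locus p 0.216 to 1 (Il1b) and 0.0192 to 0.26 (Il1r1), and r between the knockouts 0.43 to 0.49. Of named-gene results under planned settings other than left-out libraries 1349 were the same, 129 stronger, 94 weaker, 2 moved and 0 reversed; with left-out libraries 1747, 38, 199, 5 and 0; under added settings 266, 38, 19, 2 and 0. For lists these were 434, 1, 79, 18 and 0; 1168, 31, 70, 80 and 1; and 123, 5, 16, 18 and 0. Replicate numbers did not pair libraries across genotypes: residuals of equal numbers correlated at r = −0.148 to 0.0799 in 24 pairs of 2 weeks and −0.138 to 0.0476 in 9 pairs of 4 weeks, and 0 of 16 and 3 of 9 libraries matched best with their own number.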

Other observations

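The correlations of Echdc2 with CreERT2, the count of calls by chromosome and the sums of lists in VF_4w 6 were tests chosen only after the result was seen. Further genes of low p in the knockouts against the libraries labelled WT did not pass. Plac8, a gene of myeloid progenitors, was at 120 (SD 38.7) CPM in Il1r1KO against 23.96 (SD 13.6) at 2 weeks, n = 4 each (log2 2.32, SE 0.50, edgeR adjusted p = 0.122), and Kit, the stem cell factor receptor, at 688 (SD 61.3) against 1050 (SD 165) (−0.61, SE 0.13, 0.124). Angpt1, an angiopoietin made by stem cells, was at 784 (SD 100) against 1090 (SD 90.5) CPM (−0.48, SE 0.10, 0.0788), Socs2 at 290 (SD 70.3) against 125 (SD 39.1) (1.22, SE 0.25, 0.0721), and Runx3 in Il1bKO at 34.8 (SD 9.30) against 9.52 (SD 4.46) (1.87, SE 0.40, 0.12).

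Dock2 varied among the libraries labelled WT from 168 to 394 CPM, and was 128 (SD 18.9) in Il1bKO, 233 (SD 29.4) in VF and 309 (SD 51.1) in Il1r1KO. Chrnb1 fell from 24.5 (SD 4.84) CPM at 2 weeks to 8.16 (SD 2.53) at 4 weeks in Il1r1KO (log2 −1.58, edgeR adjusted p = 0.019). In VF it was at 37.7 (SD 2.59) and 18.2 (SD 6.39) CPM, which did not pass (−1.05, adjusted p = 0.36), and in Il1bKO at 38.6 (SD 7.04) and 38.1 (SD 21.8), the latter from 63.2, 24.3 and 26.8 CPM in Il1bKO_4w 5, 6 and 7. In VF_4w 6 other lists stood out beside interferon gamma: type I interferon genes were at 2.07 times, megakaryocyte genes at 2.03 times, the unfolded protein response at 1.43 times and JAK-STAT targets at 1.32 times the other VF libraries of 4 weeks, each above all other libraries, and it had most of the Il1b reads of all VF libraries (391). One hypothesis is that this mouse had an infection or inflammation at sampling; interferon genes in other cells of the same mouse would test it.

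Echdc2 may report the CreERT2 transgene, at least 1.6 times VF in both knockouts, or the human JAK2 construct, and these cannot be told apart here. The Cre is labelled Scl, another name of Tal1, and Tal1 lies on chromosome 4 with Echdc2, which held 4 of the 6 genes called in Il1bKO against the libraries labelled WT (Fisher exact p = 2.0e-04). Reads crossing from the transgene into Tal1 sequence would show whether the higher Tal1 comes from the transgene itself. Donors with the Cre but without the JAK2 construct, genotyped by CreERT2 reads, would separate these. The chromosome 1 genes lower in Il1r1KO may come from strain sequence (Fisher exact p = 0.0306 within 20 Mb, which covers Trak2 and Mpp4 alone; 1 within 10 and 5 Mb, 0.287 in limma voom, 0.377 in a fit of the compared groups alone and 0.165 to 0.26 without any of 12 of 14 libraries). Variants in the reads of these genes, and of Lancl1 and Wdfy1 outside that window, would show it or rule it out. The same reading of variants could be applied to Mid1, Wdfy1 and Srp54b, which also differed among the libraries labelled WT (Srp54b 62.1, 62.8, 101 and 94.6 CPM).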
